A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

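Total RNA was taken from 2 yeast strains, wild type JA100 and its tetO:HAL3 vhs3::URA3 derivative, and cDNA was primed with oligo(dT) from 8 µg of RNA and labelled indirectly with Cy3 or Cy5, per the labels' protocols. The 3 arrays stand for 2 biological replicates according to the labels, with a dye swap of the first. Each array was assigned to its replicate and dye orientation from the labels alone.

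The deposited table holds 1 log2 ratio per gene and array, and the authors' scanner output, background correction, spot filter and normalization are not given in the sources used here. The log base, direction and centring were worked out from the values. Read as log2 in the deposited direction, 100% of the ratios on each array are whole multiples of 0.001 to the rounding of the table, against 9.66 to 10.8% with the sign turned and similar shares for natural or decimal logarithms. The medians as deposited were 0.0229, 0.0072 and 0.0468. The swapped array correlated positively with its partner (r of 0.508), so it had been turned already and was not turned again. The common direction was read as Cy5 over Cy3 on the arrays with the mutant in Cy5, that is mutant over wild type, to be turned only if VHS3 and HAL3 were both higher on every array, which they were not. That rule alone does not choose a direction. Which channel is the numerator is not stated, so the reading rests on the dyes in the labels and on VHS3 and HAL3 being lower that way on both arrays of replicate 1. What a blank means is also not stated. Blanks were left out, and intensities were not used here, so the distance of a signal from background is unknown for every ratio.

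Each array was centred on its median. The dye-swap pair, made from the same RNA extracts, was averaged into 1 replicate, using the 1 value present where the other was blank. Genes needed a value in both replicates, which left 4598, of which 4258 were measured on all 3 arrays. Names came from a RefSeq table of the assembly R64, used for names and chromosomes only, since the array's own build is not given in the sources used here. It matched 5662 of the 6212 listed identifiers and left 550 under their systematic name.

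The mean log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, n = 2, 1 residual degree of freedom per gene, prior degrees of freedom 5.15), two-sided, with Benjamini-Hochberg adjustment at 0.05. An exact sign-flip test on 2 replicates cannot give a two-sided p below 0.5, so per-gene p-values come from limma alone. Wild type was measured only as the partner channel on the same arrays, so its own spread enters through the ratios. Genes at least 2-fold different in both replicates were counted beside the test. Tested on simulated data for this comparison (4598 genes, 200 changed, 20 draws), the procedure called 25.3% of genes changed 2-fold, 95.3% of those changed 4-fold, 99.4% of those changed 8-fold and 0.282% of unchanged genes. A shifted list was called in 100% of draws and 0.1 unshifted lists per draw. The simulation drew genes independently, with the same true change and spread in both replicates. On the arrays the SD was 0.650 and 0.699 in replicate 1 and 0.353 in replicate 2. The estimated inter-gene correlation was 0.638 for the PHO list and 0.812 for ribosome biogenesis. These rates therefore describe an easier case than the data, and may be too favourable for genes and lists alike.

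Gene lists, 49 in number, were written from textbook knowledge before the data were examined, as were the design, the test and the alternatives except those named as added. Of 1301 list entries 1298 matched a locus. Lists with at least 5 measured genes (46) were tested with camera at an inter-gene correlation of 0.01, with an estimated correlation and with fry. The last 2 rest on 1 residual degree of freedom, so after adjustment over 46 lists a list could hardly pass by them. The list of the altered genes HAL3, VHS3 and URA3, the list of genes encoded in mitochondria with 0 measured and the alpha-specific list with 2 measured (medians −0.10 and −0.28) were not tested. Each list's median was also set against 10000 random lists of the same size per replicate, without matching on expression.

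The genes named were fixed by rule. They were HAL3, VHS3, URA3, CAB3, PPZ1 and PPZ2, then up to 12 genes per direction with the largest mean change past the threshold and the same sign on all 3 arrays, with places left open going to genes at least 2-fold different in both replicates. As 0 genes passed, the 12 higher and 6 lower genes named did not pass the test. In each list described, up to 4 members with the largest mean change and the same sign on all 3 arrays could be named, and members past the threshold adjusted over the list alone were named besides, chosen after their values were seen.

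The alternatives changed the treatment of the dye-swap pair, the dye effect, centring, scale and quantile normalization, the variance prior, the threshold and fold limit, missing values, the list test and the replicate left out. Added after seeing the data were tests without chromosome IX, with each chromosome centred on its own median, and without HAL3, VHS3 and URA3, the random lists, and the counts within replicate 1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.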

Results

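Transcript levels of a budding yeast strain short of HAL3 and VHS3 were compared with those of its wild type on 3 spotted DNA arrays with 2 colours. Hal3 and Vhs3 are regulatory subunits that inhibit the protein phosphatase Ppz1, and together with Cab3 they form phosphopantothenoylcysteine decarboxylase (PPCDC), an enzyme of coenzyme A synthesis. In the mutant, VHS3 was replaced by the URA3 marker and HAL3 stood behind a tetO promoter, which doxycycline switches off. Both strains had the JA100 background and grew for 15 h at 28 °C in synthetic complete medium with 100 µg/ml doxycycline. The comparison thus asks what deletion of VHS3 with repression of HAL3 does to transcript levels when the drug is present in both cultures. The labels describe 2 biological replicates. Replicate 1 was hybridised on 2 arrays with the dyes exchanged, and these were averaged into 1 value per gene, while replicate 2 was hybridised on 1 array with the mutant in Cy5. Of 6212 genes listed, the arrays held a ratio for 4894 (replicate 1, mutant in Cy5), 4822 (replicate 1, mutant in Cy3) and 4728 (replicate 2), and 912 genes were blank on all 3. The number of arrays limits the precision of every value given here.

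VHS3 and HAL3 were lower in the mutant on both arrays of replicate 1 and near 0 on the array labelled replicate 2. VHS3 (YOR054C), the deleted gene, had a log2 ratio of mutant over wild type of −2.06 and −2.50 on the dye-swap pair and of 0.09 on the array labelled replicate 2. HAL3 (YKR072C, listed as SIS2 in RefSeq) was at −1.33, −1.29 and −0.14 in the same order. URA3, the marker gene, was at −1.40, −0.82 and −0.33. CAB3, the remaining PPCDC subunit gene, was at −0.99, 0.39 and −0.18. PPZ1 and PPZ2, which encode the phosphatases that Hal3 and Vhs3 bind, were at 0.17, −0.60 and 0.33, and at −0.28, −0.88 and −0.59. None of these 6 genes passed the test over all genes, the smallest adjusted p among them in limma being 0.925. VHS3 thus went against the label of the replicate 2 array, and every direction below that rests on the array labelled replicate 2 carries that mismatch. Which part of VHS3 was deleted, and where the spotted probe lies in it, is not given in the sources used here.

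**Figure D1:**
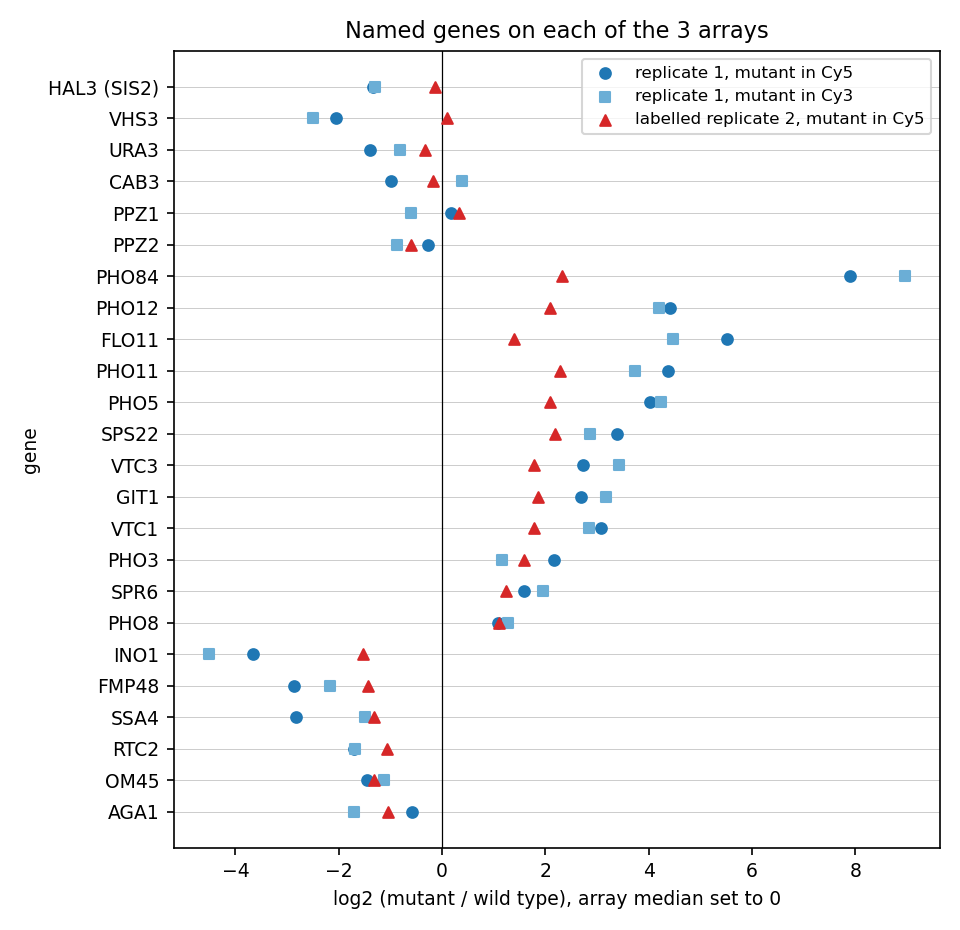
Log2 ratio of mutant over wild type (x axis, array median set to 0) for 24 named genes (y axis) on each of the 3 arrays, with 1 point per array and no error bars. VHS3 is at −2.06 and −2.50 on the arrays of replicate 1 and at 0.09 on the array labelled replicate 2, whereas PHO84 is above 2 on all 3.

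Genes of phosphate acquisition were among those with the highest ratios in both replicates. PHO84 (YML123C), the high-affinity phosphate transporter of the plasma membrane, was 344-fold higher in the mutant in replicate 1 and 4.99-fold higher on the array labelled replicate 2, a mean log2 ratio of 5.37 ± 4.32 (SD, n = 2). The secreted acid phosphatase genes PHO5, PHO11 and PHO12 were 17.5, 16.5 and 19.8-fold higher in replicate 1 and 4.26, 4.84 and 4.25-fold higher on the array labelled replicate 2. GIT1, which takes up glycerophosphoinositol, and VTC1 and VTC3, subunits of the vacuolar polyphosphate polymerase, had mean log2 ratios of 2.40 ± 0.75, 2.37 ± 0.84 and 2.42 ± 0.92 (SD, n = 2). PHO3, a constitutive acid phosphatase, and PHO8, the vacuolar alkaline phosphatase, had 1.62 ± 0.06 and 1.14 ± 0.05 (SD, n = 2), the small SD of PHO3 resting on the average of 2.17 and 1.17 on the dye-swap pair. PHO3, PHO5, PHO11 and PHO12 are close relatives in sequence, so a spotted probe of one may also bind transcripts of another and their values are not independent.

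Outside phosphate metabolism, FLO11 (YIR019C), a cell surface flocculin needed for adhesion and invasive growth, was 31.7-fold higher in replicate 1 and 2.62-fold higher on the array labelled replicate 2. SPS22, a sporulation gene with a role in the spore wall, was 8.73-fold and 4.57-fold higher, and SPR6, a gene expressed in sporulation, was 3.40-fold and 2.37-fold higher. In the other direction INO1 (YJL153C), inositol-3-phosphate synthase, was 17.0-fold lower in replicate 1 and 2.88-fold lower on the array labelled replicate 2. FMP48, a gene for a predicted protein kinase, had log2 ratios of −2.52 and −1.43, and SSA4, a heat-inducible chaperone of the Hsp70 family, of −2.16 and −1.33. RTC2, a vacuolar transporter of basic amino acids, was at −1.70 and −1.07. OM45, a protein of the mitochondrial outer membrane, was at −1.28 and −1.33, and AGA1, the anchor subunit of a-agglutinin, at −1.14 (−0.58 and −1.70 on the dye-swap pair) and −1.05. FLO11 and OM45 lie on chromosome IX, whose median log2 ratio in replicate 1 was −0.72. FMP48 lies on chromosome VII. On the array labelled replicate 2, VII and VIII held 46.9% of the genes at least 2-fold lower, against 14.6% of the genes measured. The arrays do not tell strands apart, and the PHO84 and FLO11 loci are known to carry noncoding transcripts as well.

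These 18 genes were among 19 that differed at least 2-fold in the same direction in both replicates, 13 of them higher and 6 lower in the mutant. The nineteenth, YAR068W, was at 1.02 (1.49 and 0.55 on the dye-swap pair) and 1.24 and is named here after its value was seen. Independent replicates with the same marginal counts would share 0.411 higher and 3.46 lower genes. The reading frames YGR164W and YHL037C, both picked out after their values were seen, went opposite ways at that size, at 1.36 and 1.29 in replicate 1 and −2.12 and −1.28 on the array labelled replicate 2. For YGR164W the replicate 1 value came from the array with the mutant in Cy5 alone, the swapped array being blank. By test, 0 of 4598 genes passed a Benjamini-Hochberg adjusted p of 0.05 in limma, with 222 at an unadjusted p under 0.05, of which 64 were higher and 158 lower in the mutant. The smallest adjusted p was 0.258, shared by PHO11, SPS22, VTC1, VTC3, GIT1 and PHO3, while PHO84, with the largest ratio but also the largest gap between replicates, had 0.673. Fitting the 3 arrays as if independent called 17 genes, 16 of them in the group of 19 plus GAC1, but that setting counts the dye-swap pair as 2 replicates.

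**Figure D2:**
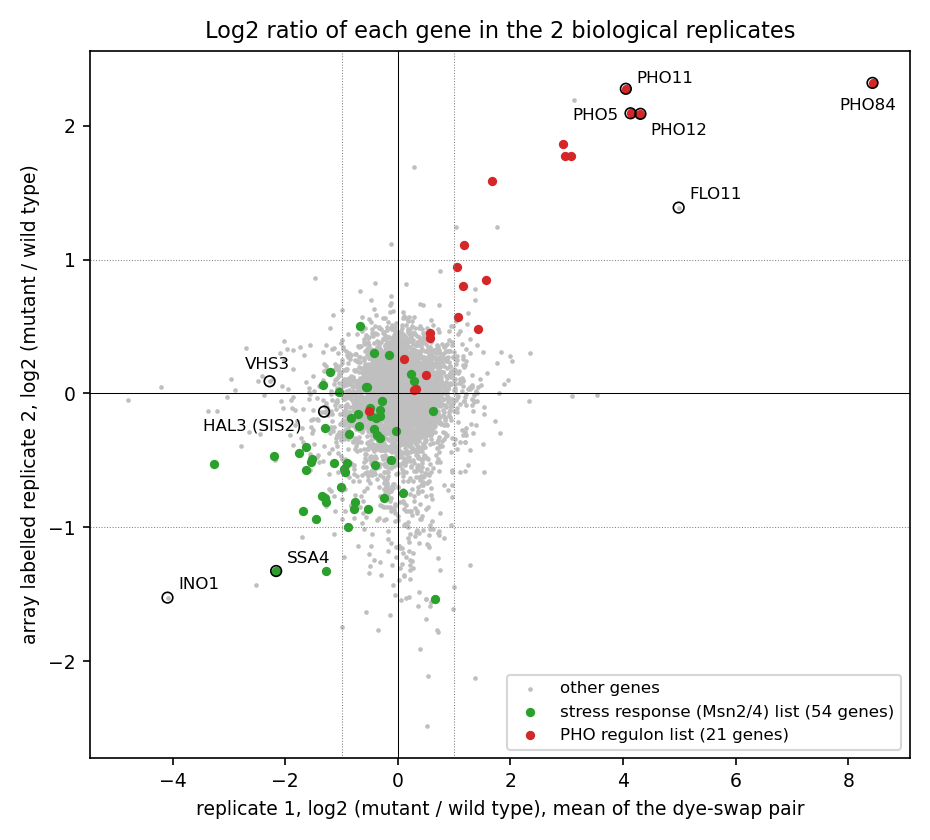
Log2 ratio of mutant over wild type of each gene in replicate 1 (x axis, mean of the dye-swap pair) against the array labelled replicate 2 (y axis), with dotted lines at 2-fold. The 21 genes of the PHO list (red) lie mostly in the upper right, the 54 genes of the Msn2 and Msn4 stress list (green) mostly in the lower left, and VHS3 and HAL3 near 0 on the y axis.

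Ratios correlated less between replicates than within the dye-swap pair. Across genes, which are not independent replicates, Pearson's r was 0.508 between both arrays of replicate 1 (Spearman's rho 0.288, 4546 genes) and 0.159 between replicate 1 and the array labelled replicate 2 (rho 0.0723, 4598 genes). Without the PHO list that r was 0.0858. The SD of the log2 ratios was 0.650 and 0.699 on the arrays of replicate 1 and 0.353 on the array labelled replicate 2. On both arrays of replicate 1, 55 genes were at least 2-fold higher and 119 at least 2-fold lower. Of the higher ones 38 of 52 measured were above 0 on the array labelled replicate 2, and of the lower ones 68 of 106 were below 0.

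The PHO list was higher, and the Msn2 and Msn4 and the Hsf1 lists lower, in both replicates by their medians. In the PHO list, targets of the transcription factor Pho4 and genes of phosphate and polyphosphate handling, 20 of 21 measured genes were above 0 in both replicates, with medians of 1.18 in replicate 1 and 0.84 on the array labelled replicate 2. The list was shifted upward by camera at an adjusted p of 1.47e-22, and had adjusted p = 0.931 with an estimated correlation. Adjusted over the list alone 14 of its genes were higher, against 0 over all genes tested. Besides those described above, these were PHO81, the inhibitor of the Pho80-Pho85 kinase, at 1.57 and 0.84, VTC2 at 1.06 and 0.94, VTC4 at 1.16 and 0.80, PHO86 at 1.07 and 0.57, and SPL2 at 1.43 and 0.48. GPP2, a glycerol phosphatase, was the 1 member below 0 in both replicates. PHO3 is also in the G2/M and thiamine lists, where it was the 1 gene past the threshold adjusted over the list alone, and INO1 had that place in the zinc list, although none of these lists was shifted.

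The list of Msn2 and Msn4 stress targets had 41 of 54 measured genes below 0 in both replicates and 2 above. Its medians were −0.76 in replicate 1 and −0.42 on the array labelled replicate 2, with a camera adjusted p of 2.06e-21 and adjusted p = 0.931 with an estimated correlation. Adjusted over the list alone 20 genes were lower, against 0 over all genes. HSP12, a small membrane-binding stress protein, was at −3.27 and −0.52, XBP1 on chromosome IX, a transcriptional repressor induced by stress, at −2.21 and −0.46, and the trehalose genes TSL1 and TPS2 at −1.30 and −0.78 and at −0.77 and −0.87. In the Hsf1 heat shock list, 18 of 24 genes were below 0 in both replicates and 0 above, with medians of −0.61 and −0.34 and a camera adjusted p of 2.81e-12 (adjusted p = 0.931 with an estimated correlation). Adjusted over the list alone 6 of them were lower, against 0 over all genes, namely SSA4, HSP26, HSP78, HSP104, HSP30 and BTN2. HSP26, a small heat shock chaperone, was at −1.45 and −0.94, and HSP78, a chaperone of the mitochondrial matrix, at −1.63 and −0.57. Some genes, such as SSA4 and HSP104, are in both lists.

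Ribosome genes were higher in replicate 1 with little shift on the array labelled replicate 2. Ribosome biogenesis genes had a median of 0.75 in replicate 1 and 0.02 on the array labelled replicate 2 (102 measured, 49 above 0 in both, camera adjusted p of 5.90e-16), with adjusted p = 0.931 with an estimated correlation. UTP18, SOF1 and UTP23, components of the small subunit processome, were at 1.21 and 0.33, 1.14 and 0.37, and 1.20 and 0.24. The 129 genes of cytosolic ribosomal proteins had medians of 0.39 and −0.01 (adjusted p of 1.21e-06, and adjusted p = 0.931 with an estimated correlation), with 115 of them above 0 in replicate 1 and 63 on the array labelled replicate 2. Its examples differed with the dye, RPL29 being at 1.35 and 0.11 on the dye-swap pair and 0.46 on the array labelled replicate 2, and RPS14A at 0.97, 0.01 and 0.45. The mitochondrial ribosome list was at 0.19 and 0.03 (58 genes, adjusted p of 0.0240) and had adjusted p = 0.931 with an estimated correlation. In none of these 3 lists did a gene pass adjusted over the list alone or over all genes.

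Sugar use and amino acid synthesis were lower in replicate 1 and close to or above 0 on the array labelled replicate 2. Hexose transporter genes had the lowest median of any list tested in replicate 1, −1.21, against −0.15 on the array labelled replicate 2 (11 genes, 7 below 0 in both, camera adjusted p of 3.99e-05, adjusted p = 0.931 with an estimated correlation). HXT6, a high-affinity transporter with a near-identical neighbour in HXT7, was the 1 member lower adjusted over the list alone, at −1.28 and −0.84, against 0 over all genes. HXT7 was at −1.83 and −0.24, and a spotted probe of either may bind transcripts of both. The value of HXT6 on the array labelled replicate 2 was thus not shared by its neighbour. HXT3 was at −1.83 and −0.12. Gcn4 targets of amino acid synthesis had medians of −0.68 and 0.09 (58 genes, 16 below 0 in both, adjusted p of 2.07e-05), and adjusted p = 0.931 with an estimated correlation. Among them ARG3, ornithine carbamoyltransferase, was at −4.80 and −0.05, ARG8 at −1.69 and −0.36, and LYS2 at −1.54 and −0.25. Glycolysis (24 genes) was at −0.49 and 0.08, glucose-repressed carbon use (18 genes) at −0.88 and 0.09, and osmostress with glycerol synthesis (13 genes) at −0.55 and 0.02. Their camera adjusted p was 0.00375, 0.00488 and 0.00827, each with adjusted p = 0.931 with an estimated correlation. MDH2, cytosolic malate dehydrogenase, was at −2.79 and −0.39, PYK2, a pyruvate kinase, at −1.26 and −0.10, and GPD1, glycerol-3-phosphate dehydrogenase, at −0.74 and −0.14. None of the members of these last 4 lists passed adjusted over the list alone or over all genes. With the arrays that had the mutant in Cy5 only, the adjusted p was 0.0934 for glycolysis, 0.0921 for glucose-repressed genes and 0.0724 for osmostress.

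**Figure D3:**
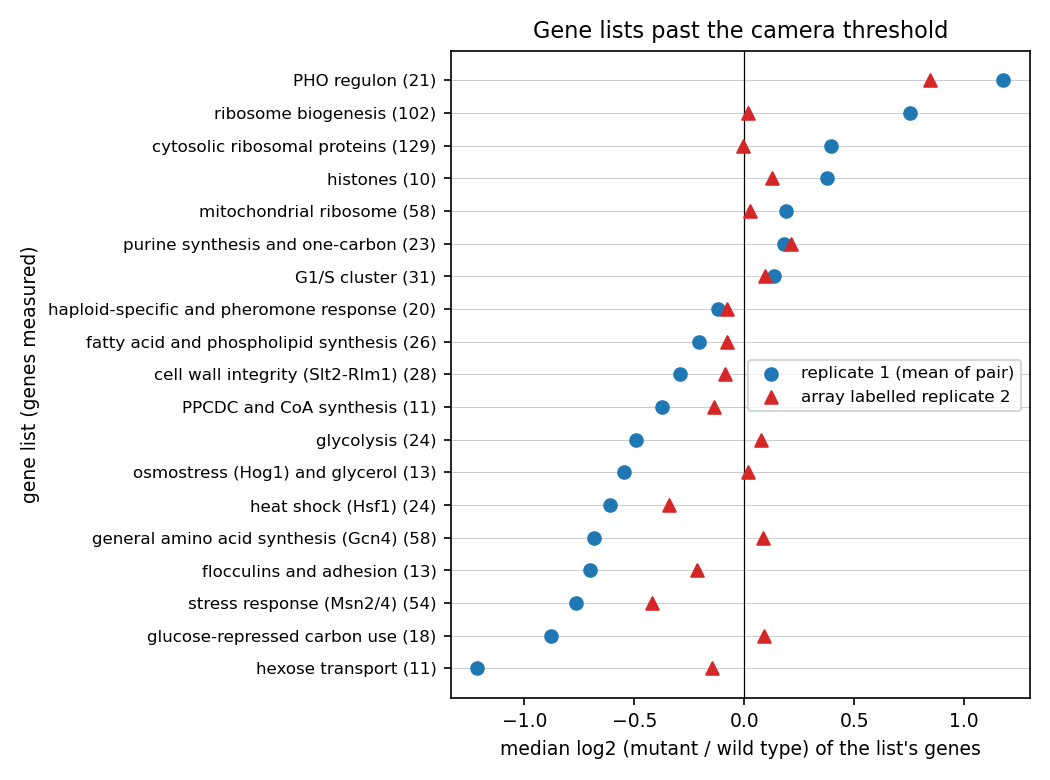
Median log2 ratio of mutant over wild type (x axis) of the 19 gene lists past the camera threshold (y axis, genes measured in brackets), in replicate 1 and on the array labelled replicate 2, without error bars. The PHO list has 1.18 and 0.84 and the stress list −0.76 and −0.42, while ribosome biogenesis has 0.75 and 0.02.

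The PPCDC, lipid, flocculin, cell wall and haploid lists made up the other lists shifted downward. The PPCDC and coenzyme A synthesis list was at −0.37 in replicate 1 and −0.14 on the array labelled replicate 2 (11 genes, 6 below 0 in both, camera adjusted p of 0.00518, adjusted p = 0.931 with an estimated correlation). HAL3 and VHS3 are members of it, and with HAL3, VHS3 and URA3 left out its adjusted p was 0.0356. CAB2, phosphopantothenoylcysteine synthetase, was at −0.57 and −0.14, no lower in replicate 1 than the median of its chromosome IX (−0.72), and CAB4, which acts in a later step of the pathway, at −0.13 and −0.88. CAB4 lies on chromosome VII, which together with VIII was rich in lower genes on the array labelled replicate 2. Lipid synthesis genes were at −0.21 and −0.08 (26 genes, adjusted p of 0.00518), among them, besides INO1, OPI3 and CHO1 of phosphatidylcholine and phosphatidylserine synthesis at −3.38 and −0.13 and at −1.87 and −0.38. This list too had adjusted p = 0.931 with an estimated correlation. The flocculin and adhesion list was at −0.70 and −0.21 (13 genes, adjusted p of 0.00518, adjusted p = 0.931 with an estimated correlation), although FLO11 itself was higher. Adjusted over the list alone FLO11 was higher and AGA1 and MGA1 lower, against 0 over all genes, and FLO8, an activator of FLO11, was at −1.56 and −0.45. Cell wall integrity genes were at −0.29 and −0.09 (28 genes, adjusted p of 0.0122), with SED1 at −0.63 and −0.97. Haploid and pheromone genes were at −0.12 and −0.08 (20 genes, adjusted p of 0.0122), with STE5 at −0.58 and −0.48 and only AGA1 lower adjusted over the list alone. Both had adjusted p = 0.931 with an estimated correlation. With the arrays that had the mutant in Cy5 only, the flocculin, cell wall and haploid lists had adjusted p of 0.184, 0.551 and 0.116.

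Purine, histone and G1/S genes made up the other lists shifted upward. Purine and one-carbon genes were at 0.18 in replicate 1 and 0.21 on the array labelled replicate 2 (23 genes, 12 above 0 in both, camera adjusted p of 0.00488), and had adjusted p = 0.931 with an estimated correlation. ADE1 and MTD1 were at 0.98 and 0.50 and at 0.95 and 0.50. Of 10 histone genes 9 were above 0 in both replicates, with medians of 0.37 and 0.13 (adjusted p of 0.00832, adjusted p = 0.931 with an estimated correlation). The G1/S list was at 0.14 and 0.09 (31 genes, adjusted p of 0.0478, adjusted p = 0.931 with an estimated correlation), with the cyclin gene CLN1 at 0.75 and 0.30. The camera adjusted p of the G1/S list was 0.0523 without the genes of chromosome IX, and 0.425 with the arrays that had the mutant in Cy5 only. With the dye as a coefficient, histones had 0.0604, G1/S 0.137 and the mitochondrial ribosome 0.0870. No member of the purine, histone and G1/S lists passed adjusted over the list alone or over all genes.

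In all, 7 of 46 lists were shifted upward and 12 downward by camera at its preset correlation of 0.01. That setting takes genes as nearly independent, so its p-values rest mainly on the spread over genes, not between the 2 replicates. Estimated correlations of these 19 lists ran from −0.0277 (purine synthesis) to 0.812 (ribosome biogenesis). Where genes of a list move together, the preset p-values overstate the evidence. With an estimated correlation 0 passed, and by fry, which asks whether a list's genes move on balance one way, 0 passed, with 2 lists at an unadjusted p under 0.05, purine synthesis at 0.0239 and the retrograde response at 0.0327. Both rest on 1 residual degree of freedom and could hardly pass a list, so their outcome decides neither for nor against any list. Purine synthesis had an estimated correlation of −0.0277, below the preset one. Its unadjusted camera p still went from 0.000986 to 0.171. In 14 of the 19 lists the medians of both replicates were on the same side of 0, and in 5 they were on opposite sides. Set against 10000 random lists of the same size, which describes these arrays and is no test, the PHO median stood at percentile 100 in replicate 1 and 100 on the array labelled replicate 2, and the stress and heat shock medians at 0 in both. Ribosome biogenesis stood at 100 and 72.9, and Gcn4 targets at 0 and 99.2. The other 27 lists did not pass, the smallest adjusted p among them being 0.0686. Monovalent cation transport, a process that Hal3 and Ppz1 control, had medians of −0.08 in replicate 1 and −0.02 on the array labelled replicate 2 (10 genes, adjusted p of 0.994), and the Ppz phosphatases and their partners −0.12 and 0.03 (8 genes, 0.994). Calcineurin targets were at −0.22 and −0.11 (16 genes, 0.259) and the iron regulon at −0.17 and 0.12 (22 genes, 0.994).

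Genes of chromosome IX were lower as a whole in replicate 1. Their median log2 ratio was −0.80 with the mutant in Cy5 (quartiles −1.31 and −0.46) and −0.60 with the mutant in Cy3 (quartiles −1.06 and −0.23), and −0.05 on the array labelled replicate 2. Over both arrays of replicate 1 the median was −0.72 (185 genes), 1.64-fold lower, while the medians of the other chromosomes lay between −0.04 and 0.10. Chromosome IX held 25 of the 119 genes that were at least 2-fold lower on both arrays of replicate 1. Without its genes, 17 genes in place of 19 differed at least 2-fold in both replicates, and 18 of the 19 lists kept their call.

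**Figure D4:**
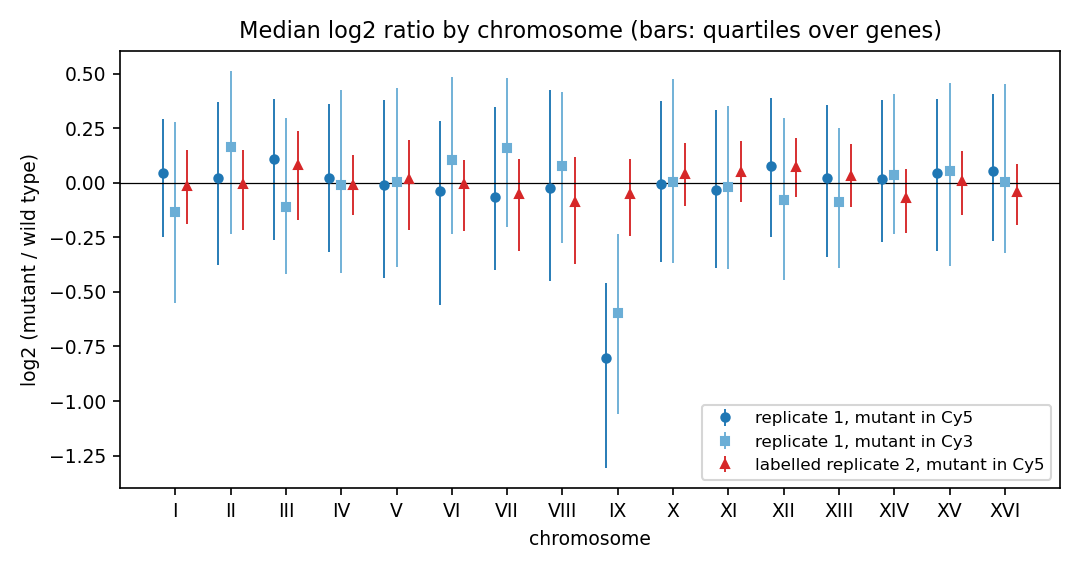
Median log2 ratio of mutant over wild type (y axis) of the genes of each chromosome (x axis) on each array, with bars from the lower to the upper quartile over genes. Chromosome IX is at −0.80 and −0.60 on the arrays of replicate 1 and at −0.05 on the array labelled replicate 2.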

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

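The settings without chromosome IX, with each chromosome centred on its own median, and without HAL3, VHS3 and URA3 were chosen only after the results were seen, and the others before the data were examined. The count of genes past the limma threshold, 0 with 222 at an unadjusted p under 0.05, stayed 0 as deposited, with a dye coefficient, with the Cy5 orientation alone, with robust eBayes, with genes measured on all 3 arrays, at an adjusted p under 0.1, and without chromosome IX. It was 17 with the 3 arrays taken as independent, 13 with the swapped array and the array labelled replicate 2, 12 after quantile normalization and 4 with arrays scaled to the same median absolute deviation (PHO5, PHO11, PHO12 and INO1). The first of these counts technical arrays as replicates, and the cause of the others was not tested. The median in place of the mean for repeated rows moved nothing, each gene having 1 value, and a random block for the replicate (duplicateCorrelation) could not be fitted. The ratio on each array already pairs the strains, so no further pairing was fitted. Genes at least 2-fold different in both replicates, 19, numbered 17 at 2-fold on each of the 3 arrays (12 higher, 5 lower, without AGA1 and YAR068W), 71 at 1.5-fold (21 higher, 50 lower), 8 at 3-fold, 23 with scaled arrays (14 higher), 27 with the dye effect removed, and 106 to 301 with 1 replicate left out, the lower count coming from the array labelled replicate 2. The 19 shifted lists became 12 with the Cy5 orientation alone, 0 with an estimated correlation and 0 by fry, 16 of them kept their call with a dye coefficient, 18 without chromosome IX, and 19 in the other settings. For genes and lists, the dye coefficient was fitted to the 3 arrays. It thus counts the dye-swap pair as separate replicates and gives replicate 1 more weight. The camera adjusted p became 9.48e-09 for Gcn4 targets and 1.97e-25 for ribosome biogenesis, and 1.65e-14 for the PHO list. Among 24 named genes, 71 of 72 values under other settings kept their direction, PPZ1 turning to −0.18 with a dye coefficient. With 1 replicate left out 46 of 48 did, VHS3 ranging from −2.28 to 0.0907 (without replicate 1) and PPZ1 from −0.22 (without the array labelled replicate 2) to 0.33. With 1 replicate there are no residual degrees of freedom, so these are values without a test. All named genes but HAL3, VHS3, URA3, CAB3, PPZ1 and PPZ2 had been picked for the same sign on all 3 arrays. For those picked genes a kept direction was fixed in advance and is no support. Intensities were not used here, so what signal over background limits stays open.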

Other observations

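The tests of the 3 patterns weighed here were chosen only after the results were seen, and so were the genes in this paragraph and the next. Replicate 1 held strong differences that the array labelled replicate 2 lacked. Among the lowest genes of replicate 1, ARG1, argininosuccinate synthetase, was at −4.21 (0.05 on the array labelled replicate 2), MET13, methylenetetrahydrofolate reductase, at −3.04 (−0.02), LYS1 on chromosome IX, the last step of lysine synthesis, at −2.89 (0.03), CYB2, lactate dehydrogenase of the mitochondrial intermembrane space, at −2.71 (0.34), PUT4, the proline permease, at −2.64 (−0.29) and LEU1, isopropylmalate isomerase, at −2.48 (0.09). Each was lower on both dye orientations of that replicate, as the rule that picked them required. Genes picked as extremes of 1 replicate also tend to lie nearer 0 in another.

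Among genes higher in replicate 1, PTR2, a transporter of small peptides, was at 3.09 (−0.02 on the array labelled replicate 2), IRC7, a carbon-sulfur lyase, at 2.33 (−0.06), BAT2, the cytosolic branched-chain aminotransferase, at 2.03 (0.24), HPT1 of purine salvage at 1.88 (0.07) and FRE1, a ferric and cupric reductase, at 1.79 (0.01). The respiratory chain list had medians of 0.43 in replicate 1 and −0.11 on the array labelled replicate 2 (32 genes, camera adjusted p of 0.0710), and the multidrug resistance list of 0.02 and −0.30 (12 genes, 0.0686). On the array labelled replicate 2, 53 of 113 genes at least 2-fold lower lay on chromosomes VII and VIII, 46.9% against 14.6% of the genes measured. FMP48, CAB4, BTN2 and MGA1, described above as lower, lie on chromosome VII.

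VHS3 and HAL3 were near 0 on the array labelled replicate 2, although PHO84, PHO5 and FLO11 were high there. A common compression of all ratios on that array would leave every gene the same share of its log2 ratio. Outside chromosome IX, 84 genes at least 2-fold lower on both arrays of replicate 1 kept a median share of 0.107 (quartiles −0.04 and 0.26). The share was 0.570 for 12 PHO genes (quartiles 0.53 and 0.65). The 84 genes were picked from all genes as extremes of replicate 1, which tend to lie nearer 0 in another replicate. The PHO genes came from a preset list, so the contrast argues only weakly against a common compression. At the median PHO share VHS3 would be at −1.30, not 0.09. PHO84 kept less than most PHO genes, at 8.43 and 2.32, so the value expected of VHS3 depends on the gene taken. Dilution of the mutant RNA with wild-type RNA cannot be told apart from the rest: VHS3 as observed, above 0, leaves no room for mutant RNA, but taken at −0.60, nearly 2 SD of the whole array lower, it allows up to 43.0%, above the lower quartile of 23.5% that the PHO genes need, and these need anything from 1.16% (PHO84) to 91.9%. RNA of a strain without the vhs3::URA3 deletion cannot be told apart either: URA1, URA3, URA4 and URA10 had a median of −0.14 on that array, but the share kept by those 84 lower genes would put them at −0.15. It would also leave HAL3 at −0.14 and the high PHO genes to some other difference, and no biological explanation was tested, as the labels name none between the replicates.

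The lower ratios of chromosome IX in replicate 1 were weighed as a dye effect or an unequal copy number. If the dyes were swapped as labelled, a dye or print effect is argued against by the median of −0.60 on the dye-swapped array, beside −0.80 on its partner. The shift was spread over the chromosome, with 92.4% of its genes below 0, against 46.6% of the others. A median does not rest on a few strong genes, so that share describes the shift and is no separate test. An unequal copy number of the chromosome between the cultures of replicate 1 may account for the shift, since the right arm had a median of −0.63 (37 genes) and the left arm −0.72 (148 genes). In log2 ratio, 1 copy against 2 would give −1 and 2 against 3 would give −0.58. Which culture would have gained or lost a copy cannot be read from a ratio, and DNA was not analysed here.

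URA1, URA3, URA4 and URA10, the pyrimidine genes activated by Ppr1, had a median of −1.39 in replicate 1 while the other 10 measured pyrimidine genes had 0.14. Those 10 ranged from −0.98 (URA8) to 0.74 (URA7), so URA8 lay below URA10, which was at −0.61. A marker effect with a wild type that has no URA3 transcript is argued against, since URA3 itself was at −1.40 and −0.82 in replicate 1 and would then be higher in the mutant. With a transcribed but inactive ura3 in the wild type, a genotype that the labels do not state, the marker may lower these targets, but their difference of −1.53 from the other genes decides nothing, because the 4 genes were picked for being low. A general fall of biosynthetic genes stays open, since the median of the 4 genes stood at percentile 5.96 among random sets of 4 amino acid synthesis genes. The pyrimidine list as a whole had medians of 0.08 and 0.03 but a mean below 0, at −0.22 (12 genes with a value in both replicates, camera adjusted p of 0.576).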
